A study of Rattus norvegicus with 62 samples.

How the data were processed

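Total RNA from brainstem, hippocampus and frontal cortex of male Wistar rats was hybridised to single-colour oligonucleotide arrays. The labels give 9 groups (phenytoin, levetiracetam or control solution in each region) of 7 rats; 62 arrays were used, because the array numbered 4 of the control frontal cortex is not analysed here. Groups and numbers came from the labels, and the regions of a treatment may come from the same rats. The labels of levetiracetam brainstem rats 1 and 2 name both drugs; they were kept in the levetiracetam group, as their sample names state, and left out in an alternative.

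The deposited table holds 1 linear intensity per probe set and array, scaled by the authors. The scaling is seen in the values: with 2 percent trimmed from each end, the mean intensity of the deposited arrays without missing values is 150 to 150.1. The summarization software, its version and detection calls are not given in the sources used here. The array numbered 4 of the phenytoin hippocampus lacks values for 4799 of the 31099 probe sets, which were left missing. No pair of arrays was identical, and the highest correlation within a group was 0.987. The rats of a group are separate per the labels' numbering, and the p-values measure the spread between these samples.

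Values below 0 were set to 0 and transformed as log2(value + 16). A rule set before the data were examined called for quantile normalization between all arrays where array medians differ by over 0.5 on the log2 scale; they ranged from 5.90 to 6.48, so it was applied, fitted on the 26300 probe sets with a value on every array. The 57 control probe sets and the dimmest 40 percent of the others in each region were left out, leaving 18625. Of the 31042 other probe sets, 20826 carry 1 gene symbol in the platform annotation, 436 several and 9780 none; 20764 were matched to the reference gene table by Entrez identifier, which changed 0 symbols. Genes are named only from probe sets with 1 symbol.

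Each region was fitted separately with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on its 3 treatments, and the 3 contrasts were tested two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences of a drug's effect between regions were tested in a fit of all 9 groups with an F test, and the regions of control rats were contrasted in the same fit. For each drug against control the named genes are the 12 largest increases and the 12 largest decreases among those that passed, or up to 12 by smallest p where fewer passed. Between the drugs they are the 6 largest each way, and from each F test the 8 smallest p. Members of the fixed lists, Sv2a and 3 sodium channel genes are named in addition. This rule, the settings and 32 gene lists were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01) on the brightest probe set per gene measured on every array, adjusted over the lists of a comparison; 31 lists had at least 5 measured genes. Lists were also tested with an estimated correlation, under which 0 lists shifted in any comparison, and with fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes. Counts adjusted over the list alone use the list's genes as the family.

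RNA quality was measured by the log2 ratio of the 3' to the 5' Gapdh and beta-actin control probe sets, and labelling and hybridisation by the mean of the spike-in control probe sets. Groups were compared with two-sided exact permutation tests, adjusted over the 9 comparisons of each measure. The outlying arrays were 4 whose estimated array weights, 0.152 to 0.311, lay far below the average.

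The models were tested on simulated data with the spread of each region. The simulated probe sets varied independently of each other, unlike real ones, so the shares may be too favourable. At a true log2 change of 0.25 the share recovered was 20 and 18 percent for phenytoin and levetiracetam in the brainstem. It was 4 and 16 percent in the hippocampus and 2 percent for both in the frontal cortex. At a true log2 change of 0.5 the share recovered was 66 and 58 percent for phenytoin and levetiracetam in the brainstem, 48 and 52 percent in the hippocampus and 38 and 44 percent in the frontal cortex. At a change of 1 it was 100 percent in brainstem and hippocampus, and 88 and 86 percent in the frontal cortex.

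Alternatives fixed beforehand were the values as deposited, a floor of 1 without a pseudocount, no filter or the dimmest 60 percent left out, all arrays in 1 fit, array weights, the Gapdh ratio as a covariate, a replicate block, an adjusted p threshold of 0.1 and 1 probe set per gene. Leaving out each array in turn, the actin covariate, leaving out the outlying arrays, refitting a gene without its outlying array and matching list symbols by synonyms were added after seeing the data. Each count was compared with 100 draws of other splits of the same arrays, and correlations between the drugs with 100 simulated draws. The splits of the tests over all regions were drawn under 2 seeds. The highest count among the other splits changed between them, from 25 to 571 for phenytoin and from 1602 to 60 for levetiracetam. The number of splits that reached the real count, the real one included, was 1 under both seeds for phenytoin, and 4 and then 3 for levetiracetam. Where the real count is 0 every split reaches it, so those splits decide nothing.

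Some tests of explanations were changed after a result was seen. The permutation test of the slopes on the Gapdh ratio was first run with 100 draws under 2 seeds, which fell on either side of its 95 percent criterion, and was then run with 100000 draws, which are the values given. A first test of hippocampal tissue in the phenytoin cortex used the called probe sets themselves, which had been selected for differing from the control cortex, and was replaced by a test on the hippocampus marker list fixed beforehand. The test of clock genes with the Gapdh covariate, first read as excluding RNA integrity, was void because that ratio did not differ between the groups, and a test with the actin ratio in the brainstem was added. Intervals of the shares kept with a covariate were added after those shares were seen. They resample arrays within groups, and with them the test of the actin ratio, first read as excluding it, no longer did. The other bootstrap intervals resample genes or probe sets, which are not independent, and so are too narrow.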

Results

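Gene expression was measured with single-colour oligonucleotide arrays in total RNA from 3 brain regions of male Wistar rats that received an antiepileptic drug or a control solution. Phenytoin, which blocks voltage-gated sodium channels, was given at 75 mg per kg and levetiracetam, which binds the synaptic vesicle protein Sv2a, at 150 mg per kg. Both drugs and the control solution were given 2 times a day through a gastric tube for 90 days. The 62 arrays form 9 groups: brainstem, hippocampus and frontal cortex of phenytoin, levetiracetam and control rats, with 7 arrays per group and 6 in the control frontal cortex. The deposited median signal of arrays without missing values lay between 34.05 and 61.79 intensity units. It was 64.05 on the phenytoin hippocampus array that lacks 4799 probe sets. The number of arrays limits the precision. Within each region 18625 probe sets were tested. Values below are normalized log2 intensities, folds are on the log2(value + 16) scale and understate changes of dim genes, errors of fold changes are standard errors (SE), and adjusted p is from limma over all probe sets of a comparison.

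The control rats show how large differences between regions were. The motor and cholinergic gene Chat, which makes acetylcholine, stood at 7.43 ± 0.44 (SD, n = 7) in the brainstem, 4.51 ± 0.29 (n = 7) in the hippocampus and 4.77 ± 0.43 (n = 6) in the frontal cortex. Prox1, a transcription factor of dentate granule cells, stood at 9.12 ± 0.19 in the hippocampus, against 7.86 ± 0.15 in the brainstem and 6.30 ± 0.12 in the frontal cortex. Mef2c, a neuronal transcription factor, was highest in the frontal cortex at 11.64 ± 0.19, against 9.59 ± 0.13 in the hippocampus and 7.65 ± 0.05 in the brainstem. Of 16 measured brainstem and spinal markers, 15 were higher in brainstem than in hippocampus. Of 23 hippocampus markers, 17 were higher in hippocampus than in frontal cortex and 3 were lower. Of 27 cortex markers, 25 were higher in frontal cortex than in brainstem. Against hippocampus 14 of them were higher in frontal cortex and 6 were lower. In all, 10509 probe sets differed between brainstem and hippocampus, 10965 between brainstem and frontal cortex, and 8579 between hippocampus and frontal cortex. The cortex samples carry titles of another style. In control rats the mean log2 signal of the spike-in control probe sets was 10.11 ± 0.15 (SD, n = 6) in frontal cortex. It was 10.68 ± 0.28 in brainstem and 11.07 ± 0.29 in hippocampus (n = 7 each). Differences against cortex can thus include differences between sets of arrays, which cannot be told apart from region.

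**Figure D1:**
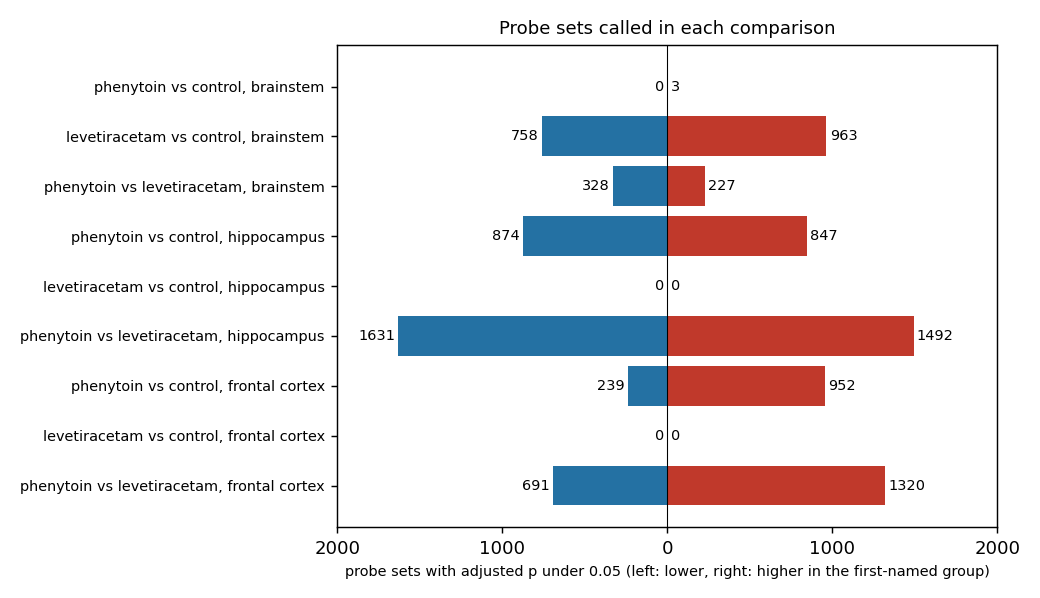
Number of probe sets with an adjusted p under 0.05 in each comparison of treatments (bars to the right, higher in the first-named group; bars to the left, lower). Levetiracetam gave 963 higher and 758 lower probe sets in the brainstem and 0 in the other regions, while phenytoin gave 3 in the brainstem.

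In the brainstem, few transcripts differed between rats given phenytoin for 90 days and control rats. Pafah1b1, a regulator of the motor protein dynein, rose 1.87-fold (log2 fold change 0.91, SE 0.16, adjusted p = 0.0324), and all 7 phenytoin arrays lay above every control array. It lost its call in 7 of 11 other settings, with adjusted p from 0.00174 to 0.404. It was the only named gene among 3 probe sets that rose, and 0 fell. At an unadjusted p under 0.05 limma counted 1360 probe sets, and leaving out single arrays gave 1 to 10 past the threshold. The named genes with the next smallest p did not pass. Among them were the chaperone Hspa4 (log2 fold change 0.90, adjusted p = 0.0538), the vesicle-priming gene Unc13c (0.37, adjusted p = 0.0538), the actin regulator Limk1 (0.61, adjusted p = 0.0538) and Zfyve9 (0.69, adjusted p = 0.0538). Further down were Rad23b (0.78), Eml2 (0.83), the myelin gene Mobp (0.24), Pabpn1 (-0.27), Swi5 (0.46), the astrocyte filament gene Gfap (-0.29, adjusted p = 0.116) and Dhx9 (0.59).

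As groups, 8 of 31 gene lists shifted in the phenytoin brainstem by camera with a preset correlation, though none of their members passed over all genes. The list of 39 ribosomal protein genes shifted up (median log2 fold change 0.09, adjusted p = 4.21e-09), and 6 of its members rose when adjusted over the list alone. With an estimated correlation its adjusted p = 0.429. Rpl35a (0.18) and Rpl24 (0.27) had its smallest p. The 65 oxidative phosphorylation genes shifted up (0.03, adjusted p = 0.0185, and adjusted p = 0.805 with an estimated correlation), with 1 member past the threshold adjusted over the list alone. The 23 cholesterol synthesis genes shifted down (median -0.11, 21 of 23 below 0, adjusted p = 1.05e-05, and adjusted p = 0.348 with an estimated correlation), with Tm7sf2 at -0.31 and Lss at -0.28 and 0 members past the threshold adjusted over the list alone. Astrocyte markers shifted down (22 genes, median -0.05, adjusted p = 0.000235, and adjusted p = 0.348 with an estimated correlation), and Gfap and Glul (-0.23) were the 2 that fell when adjusted over the list alone. Microglia and macrophage markers shifted down (27 genes, median -0.17, adjusted p = 0.000569, and adjusted p = 0.429 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. Oligodendrocyte and myelin markers shifted down (27 genes, median -0.07, adjusted p = 0.00531, and adjusted p = 0.429 with an estimated correlation), and 1 rose and 2 fell adjusted over the list alone. Glycolysis genes (28 genes, median -0.04, adjusted p = 0.0379, and adjusted p = 0.805 with an estimated correlation) and striatum markers (19 genes, median -0.08, adjusted p = 0.0190, and adjusted p = 0.569 with an estimated correlation) also shifted down, with 0 and 2 members that fell adjusted over the list alone. The log2 ratio of the 3' to the 5' beta-actin control probe set, a sign of RNA quality, was 1.55 ± 0.16 (SD, n = 7) with phenytoin and 1.38 ± 0.06 (n = 7) in controls (exact permutation p = 0.0122, 0.0455 after adjustment over 9 comparisons).

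Many brainstem transcripts differed between levetiracetam and control rats, each by a small amount. Slbp, which binds the stem-loop of histone messages, rose 2.01-fold (log2 fold change 1.01, SE 0.14, adjusted p = 0.000109), and Bex3 rose 1.90-fold (0.93, SE 0.12, adjusted p = 0.000109). In both, all 7 levetiracetam arrays lay above every control array. Acyp2, an acylphosphatase, rose 1.76-fold (0.82, SE 0.10, adjusted p = 4.33e-05). Tmem255a (0.91), the caveolin Cav2 (0.90), the small GTPase Rap2c (0.88), Art1 (0.81), the microglial receptor Gpr34 (0.80), Larp4b (0.76), Nudcd2 (0.75), the helicase Dhx9 (0.75) and the fatty acid desaturase Scd2 (0.75) rose as well. Efemp2, a matrix protein, fell by 1.05 on the log2 scale (SE 0.23, adjusted p = 0.00465). Usp30 (-0.79), Carmil3 (-0.77), Actmap (-0.77), Zfp574 (-0.74), Ap5z1 (-0.72), Dbndd1 (-0.71), Tmem151a (-0.69), Rbms2 (-0.68), the prostacyclin synthase Ptgis (-0.68), Eps15l1 (-0.67) and Akap8l (-0.67) fell. Several were dim with levetiracetam, below 5.90, the lowest array median before normalization. These were Efemp2 (4.93), Usp30 (5.16), Actmap (5.17), Dbndd1 (5.18), Ptgis (5.34), Ap5z1 (5.41), Zfp574 (5.60) and Rbms2 (5.745). Art1, which rose, was dim in controls (5.27). Ap5z1 lost its call in 5 of 11 other settings and Dbndd1 in 4 of 10. Of the 24 named genes 17 kept theirs in every setting run. Altogether 963 probe sets rose and 758 fell, of which 1 each way passed 2-fold. Across probe sets this change correlated at -0.448 with that of phenytoin in the hippocampus and at 0.452 with that of phenytoin in the frontal cortex. That is another drug in other regions, so differences between arrays that several groups share stay open here beside an effect of levetiracetam.

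None of the 31 lists shifted in the levetiracetam brainstem by camera, and single members moved within them. Of 65 oxidative phosphorylation genes 7 rose and 0 fell (9 rose adjusted over the list alone), among them Ndufb8 (0.38), Cox5a (0.33) and Sdhd (0.30). Of 39 ribosomal protein genes 6 rose and 0 fell (8 rose adjusted over the list alone), with Rpl21 at 0.46 and Rpl24 at 0.39. Of 35 heat shock and unfolded protein response genes 6 rose and 2 fell (7 and 2 adjusted over the list alone); the chaperones Hspa5 (0.36), Dnajb9 (0.43) and Hspa4 (0.56) rose, and Hsp90ab1 (-0.17) and Atf4 (-0.25) fell. Of 28 synaptic vesicle genes 4 fell and 0 rose (4 fell adjusted over the list alone): Cplx1 (-0.28), Napa (-0.24), Syp (-0.32) and Vamp2 (-0.28). Of 27 oligodendrocyte and myelin markers 6 fell and 1 rose (7 and 2 adjusted over the list alone), with Aspa at -0.47, Sox10 at -0.36 and Mobp at 0.22. Of 30 glutamate receptor and transporter genes 4 fell and 1 rose (7 and 3 adjusted over the list alone), with Homer3 at -0.45 and Grik2 at 0.41. The labels of levetiracetam brainstem rats 1 and 2 name both drugs; without these arrays the count was 1107 instead of 1721. The actin ratio was 1.49 ± 0.11 (SD, n = 7) with levetiracetam and 1.38 ± 0.06 (n = 7) in controls (exact permutation p = 0.0268, 0.0603 after adjustment over 9 comparisons), and the mean log2 signal of the spike-in control probe sets was 11.06 ± 0.24 against 10.68 ± 0.28 (exact permutation p = 0.0245, 0.0734 after adjustment). With the actin ratio as a covariate, an alternative chosen after seeing the data, the count was 1073, and 960 of the 1721 stayed called. The called probe sets kept a median of 0.959 of their change.

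**Figure D2:**
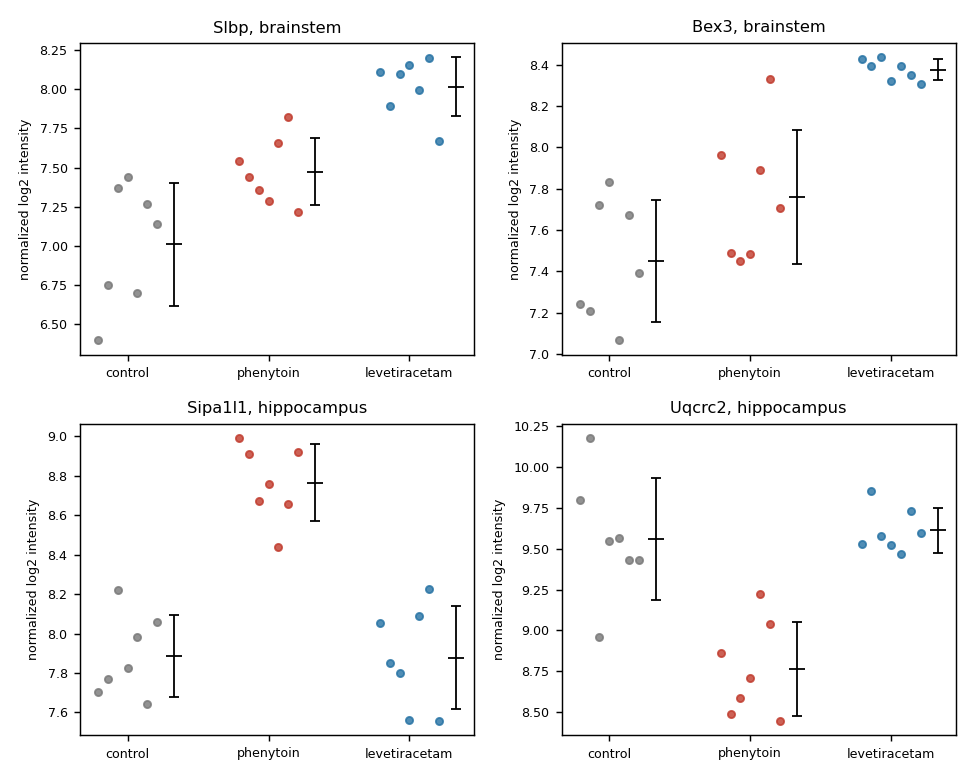
Normalized log2 intensity of Slbp and Bex3 in the brainstem and of Sipa1l1 and Uqcrc2 in the hippocampus, by treatment; points are arrays, and the bar beside them is the mean with its SD. All 7 levetiracetam arrays lie above the controls for Slbp and Bex3, and all 7 phenytoin arrays lie above the controls for Sipa1l1.

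The drugs were also set against each other in the brainstem, at doses that differ. Efemp2 was 2.28-fold higher with phenytoin (log2 difference 1.19, SE 0.23, adjusted p = 0.00703), and the tyrosine kinase Src was 1.61-fold higher (0.69, SE 0.12, adjusted p = 0.00304). Gng5 was 4.17-fold higher (2.06, SE 0.54, adjusted p = 0.0384) with an SD of 2.05 among phenytoin arrays, and Dennd6b (0.76), Wwc1 (0.75) and Zfp574 (0.74) were higher too. Gpr34 (-0.71), Lsm1 (-0.71), C18h18orf54 (-0.73), Cav2 (-0.68), Tmem255a (-0.65) and the adhesion protein gene Vcl (-0.63) were lower with phenytoin. In all 227 probe sets were higher and 328 lower, and 212 passed without levetiracetam rats 1 and 2. Leaving out single arrays gave from 221 (without phenytoin rat 3) to 893 (without phenytoin rat 1). None of the 31 lists shifted.

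In the hippocampus, transcripts differed in both directions between phenytoin and control rats. Sipa1l1, a postsynaptic regulator of small GTPases, rose 1.84-fold (log2 fold change 0.88, SE 0.11, adjusted p = 0.000434) with all 7 phenytoin arrays above every control. Camk2a, the alpha subunit of calcium/calmodulin-dependent kinase II, rose 1.95-fold (0.97, SE 0.24, adjusted p = 0.0152), and Ttll7, which adds glutamates to tubulin, rose 1.99-fold (0.99, SE 0.21, n = 6 against 7, adjusted p = 0.00765). Slx4 (0.98), Mettl17 (0.83), the T-type calcium channel gene Cacna1g (0.82), Nbas (0.82), the interferon-induced Mx2 (0.79), Spen (0.75), Ap5z1 (0.73), Secisbp2l (0.72) and Eps15l1 (0.72) also rose. Several of these were dim in controls, below 5.90, the lowest array median before normalization. Among them were Slx4 (5.13), Spen (5.25), Nbas (5.29), Cacna1g (5.33) and Mx2 (5.51). Rhoa, a small GTPase, fell by 0.95 on the log2 scale (SE 0.21, adjusted p = 0.00925) and Nek1 fell by 0.82 (SE 0.21, adjusted p = 0.0172). Rad23b (-0.96), Mal2 (-0.78), Tiparp (-0.77), Nrip3 (-0.73), the vesicle gene Vamp1 (-0.73), L3hypdh (-0.71), Rybp (-0.71), the endophilin gene Sh3gl2 (-0.70) and Galnt16 (-0.70) fell. A probe set of Uqcrc2, a subunit of respiratory complex III, fell by 0.80, and a brighter probe set of the same gene fell by 0.23. In all 847 probe sets rose and 874 fell. Of the 24 named genes 1 kept its call in every setting run. Nrip3 lost it in 8 of 10 settings (-0.82 to -0.24), Galnt16 in 6 of 10 (-0.90 to -0.21), Ap5z1 in 6 of 10 (0.41 to 0.97) and Rad23b in 5 of 10 (-1.22 to -0.40).

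A measure of RNA quality, the log2 ratio of the 3' to the 5' Gapdh control probe set, was used as a covariate. The count of 1721 hippocampal probe sets was then 17, and 16 of the 1721 stayed called. The called probe sets kept a median of 0.760 of their change. That ratio was 0.39 ± 0.10 (SD, n = 7) in phenytoin and 0.24 ± 0.12 (n = 7) in control hippocampus (exact permutation p = 0.0233, 0.105 after adjustment over 9 comparisons). Leaving out phenytoin rat 3 gave 904 probe sets and leaving out control rat 2 gave 905.

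**Figure D3:**
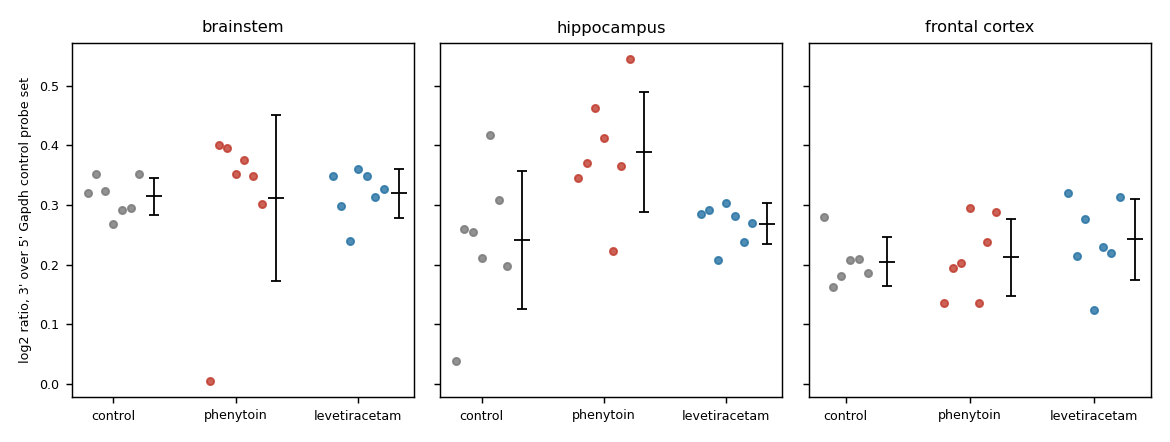
Log2 ratio of the 3' to the 5' Gapdh control probe set per array, by region and treatment; points are arrays, and the bar beside them is the mean with its SD. In the hippocampus the phenytoin mean is 0.39 and the control mean 0.24.

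Within the fixed lists, 4 of 27 synaptic vesicle genes rose in the phenytoin hippocampus and 0 fell (6 rose adjusted over the list alone): Cplx1 (0.28), Vamp2 (0.26), Syn1 (0.30) and Sv2a (0.28). These counts use the brightest probe set per gene. The Vamp1 probe set that fell, at 8.73 in controls, is dimmer than another of that gene, at 9.99, so the probe sets of Vamp1 disagree. Of 24 neuron markers 5 rose and 0 fell (5 rose and 1 fell adjusted over the list alone), namely Camk2a, Syn1, Nefh (0.45), Rbfox3 (0.40) and Elavl3 (0.47). Of 30 glutamate receptor and transporter genes 3 rose and 0 fell (3 adjusted over the list alone), Grin1 by 0.48. Of 32 potassium and HCN channel genes 3 rose and 2 fell (4 and 3 adjusted over the list alone), with Kcna6 at 0.45 and Kcna4 at -0.53. By camera 4 of 31 lists shifted. Oxidative phosphorylation genes shifted down (median -0.05, 4 of 65 fell, also 4 adjusted over the list alone, Cox5a by 0.49; adjusted p = 0.0273, and adjusted p = 0.907 with an estimated correlation). Hippocampus markers shifted down (median -0.20, 1 of 23 fell and 0 adjusted over the list alone; adjusted p = 0.0444, and adjusted p = 0.907 with an estimated correlation). Oligodendrocyte and myelin markers shifted up (median 0.18, 2 of 25 rose, also 2 adjusted over the list alone; adjusted p = 0.0273, and adjusted p = 0.907 with an estimated correlation), and Cnp rose by 0.48 and Sox10 by 0.68. Striatum markers shifted up (20 genes, median 0.33, 0 past the threshold; adjusted p = 0.0366, and adjusted p = 0.907 with an estimated correlation). The mean log2 signal of the spike-in control probe sets was 10.77 ± 0.19 (SD, n = 7) with phenytoin and 11.07 ± 0.29 (n = 7) in controls (exact permutation p = 0.0187, 0.0734 after adjustment).

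Levetiracetam left 0 probe sets past the threshold in the hippocampus by limma, with 1680 at an unadjusted p under 0.05 and a smallest adjusted p of 0.171. The genes with the smallest p, none of which passed, were Pabpn1 (log2 fold change -0.42, SE 0.08), the adhesion receptor Adgrb1 (-0.41, SE 0.08), Shprh (0.44), Car11 (-0.36), Pcdh10 (0.58), Camk1 (-0.42), the noncoding RNA Miat (-0.53), Reln (0.47), Gas5 (-0.37), Igip (0.30), Akap8l (-0.33) and Zic4 (0.47). For Pabpn1 and Adgrb1 all 7 levetiracetam arrays lay below every control. Cholesterol synthesis genes shifted down as a list (23 genes, median -0.10, adjusted p = 0.00681, and adjusted p = 0.364 with an estimated correlation), with Fdps at -0.23 and Srebf1 at -0.33 and 0 members past the threshold. Immediate early genes shifted down (37 genes, median -0.10, adjusted p = 0.0392, and adjusted p = 0.634 with an estimated correlation), with Klf4 at -0.55 and Junb at -0.31. Neither list had a member past the threshold adjusted over the list alone. Sodium channel genes (12 genes, median 0.08, adjusted p = 0.0392, and adjusted p = 0.513 with an estimated correlation) and heat shock genes (35 genes, median 0.06, adjusted p = 0.0392, and adjusted p = 0.634 with an estimated correlation) shifted up. Adjusted over the list alone, 1 sodium channel gene rose, and 1 heat shock gene rose and 1 fell.

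Between the drugs, 1492 hippocampal probe sets were higher and 1631 lower with phenytoin. Ttll7 was 2.09-fold higher (log2 difference 1.06, SE 0.21, n = 6 against 7, adjusted p = 0.00192), the collagen gene Col5a3 2.05-fold higher (1.04, SE 0.24, adjusted p = 0.00502) and Sipa1l1 1.85-fold higher (0.89, SE 0.11, adjusted p = 4.5e-05). Dennd6b (0.95), Scaf1 (0.90) and Arhgap33 (0.89) were higher as well. Rad23b was 2.83-fold lower with phenytoin (SE 0.31 on the log2 scale, adjusted p = 0.00212), and Prss35 (-1.34), Eml2 (-1.25), Pafah1b1 (-1.21), Stk32c (-1.19) and Pip5k1a (-1.14) were lower. Of these 12 named genes 7 lost their call in some other setting, and Eml2 and Stk32c did so in 3 of 11. Oligodendrocyte and myelin markers were higher with phenytoin (median 0.18, 3 of 25 past the threshold, also 3 adjusted over the list alone; adjusted p = 0.0299, and adjusted p = 0.967 with an estimated correlation). Striatum markers were higher (median 0.41, 2 of 20, also 2 adjusted over the list alone; adjusted p = 0.0299, and adjusted p = 0.967 with an estimated correlation). Heat shock genes were lower (median -0.07, 8 of 35, and 9 adjusted over the list alone; adjusted p = 0.0496, and adjusted p = 0.967 with an estimated correlation). With the Gapdh ratio as a covariate the count was 956 instead of 3123. The mean log2 signal of the spike-in control probe sets was 10.77 ± 0.19 (SD, n = 7) with phenytoin and 11.12 ± 0.13 (n = 7) with levetiracetam (exact permutation p = 0.00175, 0.0157 after adjustment). The Gapdh ratio was 0.39 ± 0.10 against 0.27 ± 0.03 (exact permutation p = 0.00932, 0.0839 after adjustment) and the actin ratio 1.45 ± 0.16 against 1.28 ± 0.12 (exact permutation p = 0.0431, 0.0776 after adjustment).

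In the frontal cortex, the largest increases of single probe sets with phenytoin were greater than in the other regions. Acyp2 rose 5.61-fold (log2 fold change 2.49, SE 0.31, adjusted p = 1.8e-05), Ankrd13c and the ubiquitin ligase adaptor Klhl2 each 4.61-fold (2.20, adjusted p = 1.28e-06 for both) and the ubiquitin-conjugating enzyme Ube2d2 4.27-fold (2.09, SE 0.18, adjusted p = 2.49e-07). Mtpn rose 4.01-fold and the translation inhibitor Pdcd4 3.74-fold; in each of these 6 genes all 7 phenytoin arrays lay above all 6 controls. Cttnbp2 (1.80), Psip1 (1.77), Fndc3a (1.71), Bpnt2 (1.69), the cAMP sensor Rapgef4 (1.67) and the lipid kinase gene Pik3ca (1.62) rose as well. Decreases were smaller: the cell surface gene Cd99 fell by 0.93 on the log2 scale (SE 0.23, adjusted p = 0.0164), the synaptic scaffold Caskin1 fell by 0.91 (SE 0.18, adjusted p = 0.00222), and the elongation factor gene Eef1a1 fell by 0.63 (SE 0.09, adjusted p = 8.75e-05). Sbf2 (-0.82), Sec14l1 (-0.73), Ddx3x-ps1 (-0.61), Hpcal1 (-0.61), Phldb1 (-0.61), Sh3bp5l (-0.61), Nelfa (-0.58), Gpam (-0.57) and Colgalt1 (-0.57) fell too. Some named genes were dim, below 5.90, the lowest array median before normalization. In controls these were Fndc3a (5.22), Bpnt2 (5.38) and Acyp2 (5.73), and with phenytoin they included Sbf2 (5.05), Sec14l1 (5.15) and Gpam (5.18). Hpcal1 lost its call in 4 of 10 other settings (-0.68 to -0.395) and Ddx3x-ps1 in 3 of 11 (-0.675 to -0.268). Of the 24 named genes 18 kept theirs in every setting run. In all 952 probe sets rose, 131 of them by over 2-fold, and 239 fell.

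Other probe sets of several of these genes did not move with the named one. A second Klhl2 probe set had a log2 fold change of -0.11 (adjusted p = 0.748), the other Mtpn probe sets -0.03 and -0.09, and of the other Pdcd4 probe sets those at -0.12 and -0.06 did not pass while that at -0.35 fell. For Ankrd13c another probe set rose by 1.52 and a brighter one stood at -0.08, and for Ube2d2 another rose by 0.40. A second Eef1a1 probe set stood at 0.11 (adjusted p = 0.490).

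**Figure D4:**
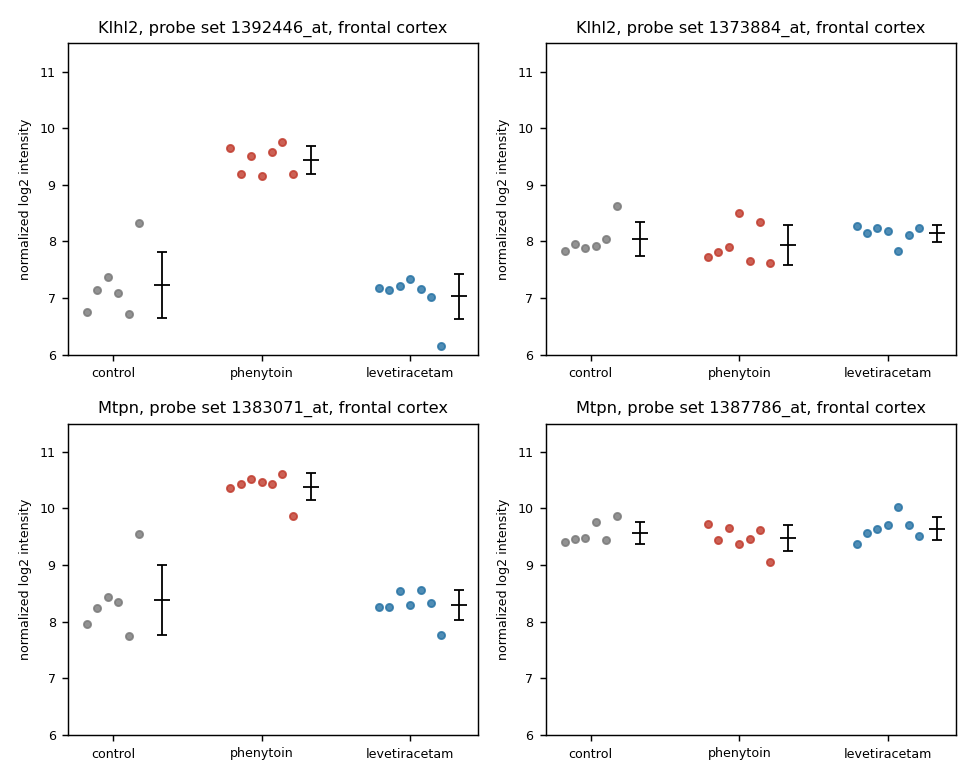
Normalized log2 intensity in the frontal cortex of the probe set named for Klhl2 and for Mtpn (left) and of another probe set of the same gene (right, chosen after its values were seen), by treatment; points are arrays, and the bar beside them is the mean with its SD. The named probe sets have log2 fold changes of 2.20 and 2.00 against control and the others -0.11 and -0.09.

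None of the 31 lists shifted by camera in the phenytoin frontal cortex. Of 24 neuron markers 4 rose and 0 fell (4 rose and 1 fell adjusted over the list alone), Map2 by 0.66, Nefl by 0.43, Eno2 by 0.36 and Vsnl1 by 0.33. Of 39 immediate early genes 2 rose (also 2 adjusted over the list alone), the cyclooxygenase gene Ptgs2 by 1.57 and Jund by 0.59. Of 30 glutamate receptor and transporter genes Gria3 rose by 0.75, while the glutamate transporter Slc1a2 (-0.32) and Grm2 (-0.52) fell (1 rose and 3 fell adjusted over the list alone). Of 65 oxidative phosphorylation genes 3 fell (also 3 adjusted over the list alone). Satb1 (0.84) among cortex markers and Crh (0.69), which encodes corticotropin-releasing hormone, rose. Of 20 hippocampus markers 0 passed (median 0.01), and of 7 brainstem and spinal markers 0 passed (median -0.05). The actin 3' to 5' log2 ratio was 1.57 ± 0.14 (SD, n = 7) with phenytoin and 1.32 ± 0.15 (n = 6) in controls (exact permutation p = 0.0152, 0.0455 after adjustment). With that ratio as a covariate, chosen after seeing the data, 644 probe sets passed instead of 1191, and 546 of the 1191 were among them. The 1191 kept a median of 0.936 of their change (median size 0.535 before and 0.5 after). Their median standard error went from 0.125 to 0.148.

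Levetiracetam left 0 probe sets past the threshold in the frontal cortex by limma, with 749 at an unadjusted p under 0.05 and a smallest adjusted p of 0.474. Dbp, a clock-controlled transcription factor, had the smallest p (log2 fold change -0.60, SE 0.12, adjusted p = 0.474), and all 7 levetiracetam arrays lay below every control. Thoc2 (0.52), Rgs17 (0.41), Tbl1x (0.53), Lsm12 (0.49), Pals2 (0.43), Tbc1d12 (0.39), Gpatch4 (0.46), Zfp91 (0.41), Mitf (0.56), Sox2 (0.57) and Dnajb14 (0.43) followed and did not pass. Oxidative phosphorylation genes shifted up as a list (65 genes, median 0.08, adjusted p = 0.000375, and adjusted p = 0.883 with an estimated correlation), as did ribosomal protein genes (40 genes, 0.07, adjusted p = 0.0301, and adjusted p = 0.883 with an estimated correlation) and apoptosis and neurotrophin genes (23 genes, 0.08, adjusted p = 0.0438, and adjusted p = 0.415 with an estimated correlation). Glutamate receptor and transporter genes shifted down (30 genes, -0.13, adjusted p = 0.0143, and adjusted p = 0.883 with an estimated correlation). In these 4 lists 0 members passed, also adjusted over the list alone. Without levetiracetam cortex array 3, which stood apart from its group, 0 lists shifted.

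Between the drugs in the frontal cortex, 1320 probe sets were higher and 691 lower with phenytoin. Acyp2 was 5.78-fold higher (log2 difference 2.53, SE 0.30, adjusted p = 5.62e-06), and Ankrd13c (2.52), Klhl2 (2.41), Mtpn (2.10), Ube2d2 (2.08) and Cttnbp2 (2.02) were higher. Caskin1 was lower (-0.97, SE 0.17, adjusted p = 0.000519), and Sbf2 (-0.91), Dennd6b (-0.77), the sterol hydroxylase gene Cyp27a1 (-0.75), Klf9 (-0.75) and Rdm1 (-0.74) were lower. Oxidative phosphorylation genes were lower with phenytoin (median -0.17, 8 of 65, and 9 adjusted over the list alone; adjusted p = 0.000144, and adjusted p = 0.973 with an estimated correlation). The actin ratio differed here too, at 1.57 ± 0.14 (SD, n = 7) against 1.26 ± 0.19 (n = 7; exact permutation p = 0.00932, 0.0455 after adjustment).

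Whether a drug's effect differed between regions was tested directly. For phenytoin 2266 probe sets differed, and the region whose effect lay farthest from the median of its 3 regional effects was the frontal cortex for 1150, the hippocampus for 1016 and the brainstem for 100. Ube2d2 had the smallest p (effects 0.08 in brainstem, -0.41 in hippocampus and 2.09 in frontal cortex, adjusted p = 6.77e-16), followed by Pdcd4, Klhl2, Suds3, Serinc1, Mtpn, Ankrd13c and Rapgef4, all highest in the frontal cortex. For levetiracetam 12 probe sets differed, with 1726 at an unadjusted p under 0.05. Among them Bex3 (0.93, 0.19 and -0.32) and Slbp (1.01, 0.17 and -0.21, adjusted p = 0.0314) had their largest effect in the brainstem, as did Tma7 (0.67 in brainstem).

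The fold changes of the drugs against the same controls correlated across probe sets with r = 0.481 in the brainstem, 0.128 in the hippocampus and 0.152 in the frontal cortex. Probe sets are not independent replicates. Simulated unchanged groups sharing those controls gave a median r of 0.5, 0.518 and 0.523. Their range was 0.189 to 0.701 in the brainstem, 0.195 to 0.782 in the hippocampus and -0.127 to 0.881 in the frontal cortex. None of the observed values lay above these ranges, and the hippocampal r lay below all 100 draws. The draws hold no drug effect, so they cannot say which r to await where many probe sets changed. The covariance was 0.0129 in the brainstem against a simulated mean of 0.00837, 0.00399 against 0.00974 in the hippocampus and 0.0057 against 0.0128 in the frontal cortex. With the controls split between the drugs, r as a mean of 2 splits was 0.149 (0.181 and 0.117), -0.084 (0.011 and -0.179) and -0.089 (-0.031 and -0.146).

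The known targets of the drugs moved little. Sv2a, the binding site of levetiracetam, rose with phenytoin in the hippocampus (log2 fold change 0.28, SE 0.08, adjusted p = 0.0282), and by 0.21 (adjusted p = 0.0478) without control rat 1, which stood apart. With levetiracetam it stood at 0.08 in brainstem, 0.12 in hippocampus and 0.07 in frontal cortex, none past the threshold, and without control rat 1 the hippocampal value was 0.05. The sodium channel gene Scn1a stood at 0.42 in the phenytoin hippocampus against control (SE 0.14, adjusted p = 0.0582) and was higher with phenytoin than with levetiracetam there (0.43, SE 0.14, adjusted p = 0.0371). Without phenytoin rat 7, which stood apart from its group for Scn1a and Scn2a, the Scn1a values were 0.28 (adjusted p = 0.0728) and 0.29 (adjusted p = 0.0491), and Scn2a passed against control (0.275, adjusted p = 0.00452). With all arrays Scn2a passed in none of the comparisons, with log2 fold changes for phenytoin of 0.09, 0.20 and 0.00 in brainstem, hippocampus and frontal cortex. Scn8a stood at 0.05 in hippocampus and -0.33 in frontal cortex with phenytoin, did not pass, and was too dim to be tested in the brainstem.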

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

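The comparisons with other probe sets of the same genes, the hippocampus marker test and the residual-component test were chosen after the results were seen, as were the actin ratio as a covariate and the interval over resampled arrays; the tests of the RNA quality ratios had their criteria set before.

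The effect of phenytoin differed between regions for 2266 probe sets. The largest difference between regions on the log2 scale was 2.50 for Ube2d2, 2.24 for Pdcd4, 2.47 for Klhl2, 0.997 for Suds3, 1.68 for Serinc1, 2.18 for Mtpn, 2.56 for Ankrd13c and 1.99 for Rapgef4, and in all of these 8 the frontal cortex was highest. The effect of levetiracetam differed for 12 probe sets, and the 8 with the smallest p differed by 0.67 for Tma7, 1.24 for Bex3, 0.85 for Tfap4, 0.74 for Fam98b-ps1, 0.64 for Sap30l, 0.92 for Srsf7-ps4, 0.81 for Scd2 and 1.22 for Slbp. In the control probe sets, outside the genes analysed, the actin 3' to 5' log2 ratio of phenytoin rats was above that of controls by 0.172 in the brainstem and by 0.253 in the frontal cortex.

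In the phenytoin frontal cortex, 429 genes had a called probe set and at least 1 other. The others changed by a median of 0.077 of the called one (95% bootstrap interval 0.039 to 0.113). Equally large region differences of control rats gave 0.263 to 0.505, and 0.505 was that of brainstem against hippocampus, without cortex arrays. The ratio was 0.175 in the levetiracetam brainstem and 0.214 in the phenytoin hippocampus, where the called changes were smaller. For the 52 such genes with an increase over 2-fold the ratio was 0.041 (interval -0.001 to 0.137), against 0.355 to 0.646 for equally large region differences, which is in line with probe sets rather than whole genes having moved in most of them; in 5 of the 52 it passed 0.5. RNA integrity stays open as a part of it: with the actin ratio as a covariate the called probe sets kept 0.936 of their change (95% interval over resampled arrays 0.629 to 1.042), and the median standard error went from 0.125 to 0.148. A large share of hippocampal tissue in the cortex samples is argued against by the 20 hippocampus markers that passed the cortex filter. They moved by 0.019 of their distance between the regions (interval -0.241 to 0.211, too narrow as it resamples genes). A smaller share is not decided, because the filter leaves out markers dim in cortex. Of the 23 markers measured over all arrays, 17 were higher and 3 lower in control hippocampus than in control cortex. Of the 1191 called probe sets, 1012 lie nearer to control hippocampus than to control cortex. They were selected for differing from control cortex, which need not bring them near hippocampus. The named Ube2d2 and Acyp2 probe sets stood low in control cortex (6.67 and 5.73) and levetiracetam cortex (6.68 and 5.69). They stood higher in phenytoin cortex (8.76 and 8.22), control hippocampus (9.39 and 9.24) and control brainstem (9.13 and 8.67). For Klhl2 and Mtpn control brainstem (7.58 and 8.49) lay near control cortex (7.23 and 8.38). A change of transcript ends with the drug, and a difference in preparation between the phenytoin and the other cortex arrays, stay open and were not tested.

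In the phenytoin hippocampus the count fell from 1721 to 17 with the Gapdh ratio. The called probe sets kept 0.760 of their change (median size 0.365 before and 0.271 after) and the median standard error went from 0.094 to 0.109, so calls ended through both. RNA integrity may contribute: slopes on the ratio within groups of the other regions correlated with the hippocampal change at r = 0.367, above 97.0 percent of 100000 permutations and so past the criterion of 95 percent, yet within the central 95 percent of permuted values (-0.374 to 0.379). A shared axis of differences between arrays stays open too: the first residual component of the arrays outside the comparison, with 22.4 percent of the variance, correlated with the change at 0.406, the levetiracetam brainstem change correlated at -0.448 with the phenytoin hippocampus change and at 0.452 with the phenytoin cortex change, and the last 2 correlated at -0.21, all without a computed chance level. An effect of phenytoin stays open beside both.

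Single arrays stood far from the rest of their group in 29 of 340 groups of values examined (8.53 percent, where chance gives about 1 in 20). Phenytoin brainstem rat 1 had a Gapdh log2 ratio of 0.005, a spike-in mean of 12.21 and a median of 6.48, and control hippocampus rat 1 had a median of 6.47, with Rybp at 7.61 and Sv2a at 8.31. Phenytoin hippocampus rat 7 had Cacna1g at 5.32, Mal2 at 6.32, Scn1a at 9.56 and Scn2a at 8.995. Phenytoin frontal cortex rat 7 had Mtpn at 9.87, Colgalt1 at 4.82 and Cyp27a1 at 5.52, and phenytoin frontal cortex rat 5 had Gpam at 4.74 and Dennd6b at 4.93. Without its outlying array Rybp stood at -0.45 in the phenytoin hippocampus, and Spen (0.66, adjusted p by limma 0.0589) did not pass. Levetiracetam frontal cortex rat 7 had Klhl2 at 6.15 and Mtpn at 7.76. The others were Pabpn1 at 10.23 in control brainstem rat 2, Gfap at 11.62 in phenytoin brainstem rat 4, Cav2 at 7.83 in levetiracetam brainstem rat 7, Zfp574 at 6.44 in levetiracetam brainstem rat 4 and C18h18orf54 at 7.07 in phenytoin brainstem rat 2. In the hippocampus they were Spen at 6.57 in phenytoin rat 3, L3hypdh at 6.07 in phenytoin rat 2, Arhgap33 at 7.78 in levetiracetam rat 7 and Sv2a at 9.05 in levetiracetam rat 1. In the frontal cortex they were Bpnt2 at 6.45 in control rat 7, Rapgef4 at 10.81 in phenytoin rat 6 and Rgs17 at 6.88 in control rat 6.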

How the results depend on the processing

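Leaving out single arrays, the actin covariate, leaving out the outlying arrays and list synonyms were chosen after seeing the data; the other settings were planned. The genes named by size or smallest p in the comparisons of treatments were rerun in the other settings, though not without each single array. None of them reversed. With the Gapdh covariate 29 calls were lost, with the actin covariate 21, without a filter 12 and with the replicate block 9. Without levetiracetam brainstem arrays 1 and 2, a setting of the brainstem alone, 11 were lost, and each other setting lost 0 to 7. Other genes of the F tests and lists were not rerun there. Causes were not tested unless named.

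For phenytoin in the brainstem the count of 3 was 0 with values as deposited, 1 without a filter, 8 with the dimmest 60 percent left out, 1 with all arrays in 1 fit, 12 at an adjusted p under 0.1, 8 without levetiracetam arrays 1 and 2, 1 without the outlying array and 1 with the actin covariate. Leaving out single arrays gave 1 to 10: 1 without phenytoin rat 1, 2 or 5, levetiracetam rat 3 or 6, or control rat 2, 3, 4 or 5; 5 without phenytoin rat 4 or control rat 6; 6 without levetiracetam rat 1, 4 or 7; and 10 without control rat 7. For levetiracetam the count of 1721 was 858 with all arrays in 1 fit, 2784 at 0.1, 1107 without levetiracetam arrays 1 and 2 and 1073 with the actin covariate, and single arrays gave 1255 to 2171. Between the drugs the count of 555 was 288 without a filter, 156 with all arrays in 1 fit, 1345 with array weights, 834 with the Gapdh covariate, 1225 at 0.1, 212 without levetiracetam arrays 1 and 2 and 893 without the outlying array. Single arrays gave 221 to 893: 893, 246, 221, 259, 892 and 288 without phenytoin rat 1, 2, 3, 4, 6 and 7, and 293, 229, 293 and 274 without levetiracetam rat 1, 3, 4 and 6.

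In the hippocampus the phenytoin count of 1721 was 2663 with array weights, 17 with the Gapdh covariate, 2956 at 0.1 and 989 with 1 probe set per gene, where fewer are tested. Single arrays gave 904 (without phenytoin rat 3) to 2510, and 905 without control rat 2. The levetiracetam count of 0 was 2 with all arrays in 1 fit, 16 with array weights and 1 without the outlying arrays, and 0 to 1 without single arrays (1 without phenytoin rat 5). Between the drugs 3123 was 956 with the Gapdh covariate, 4693 at 0.1 and 1872 with 1 probe set per gene, and 2208 to 3878 without single arrays. In the frontal cortex the phenytoin count of 1191 was 2071 with all arrays in 1 fit, 2959 with array weights, 1837 at 0.1, 626 with 1 probe set per gene and 644 with the actin covariate, and 820 to 1672 without single arrays. The levetiracetam count stayed at 0 in all settings run. Between the drugs 2011 was 3236 with all arrays in 1 fit and 1069 with 1 probe set per gene, and 1419 to 2225 without single arrays.

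Of the lists, the 8 of the phenytoin brainstem, the 4 of the phenytoin hippocampus, the 4 of the levetiracetam hippocampus and the 4 of the levetiracetam cortex were all 0 with an estimated correlation. With fry they were 0, 1, 0 and 0, while the levetiracetam brainstem went from 0 to 2 and the phenytoin cortex from 0 to 1. Without a filter the levetiracetam hippocampus had 1 and the phenytoin cortex 1, and without the outlying array the levetiracetam cortex had 0. The levetiracetam effect differed between regions for 2 probe sets without a filter, 4 without levetiracetam brainstem arrays 1 and 2 and 21 without the outlying arrays, against 12. With the controls split, the correlation of the drugs, a mean of 2 splits, was 0.149 in the brainstem (0.181 and 0.117) and reversed to -0.084 in the hippocampus (0.011 and -0.179) and -0.089 in the frontal cortex (-0.031 and -0.146); the shared controls, by construction, are then gone.

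Replicate numbers did not pair the treatments of a region: same-numbered arrays correlated on average between -0.231 and 0.067. With the number as a replicate block, the counts for phenytoin, levetiracetam and between the drugs were 4, 1589 and 399 in the brainstem, 1221, 0 and 2648 in the hippocampus and 777, 0 and 1604 in the frontal cortex, and the lists of the levetiracetam hippocampus and cortex were 2 and 8. Same-numbered arrays of different regions of a treatment correlated on average by 0.055 to 0.159, and arrays of other numbers by -0.026 to -0.009. Between brainstem and hippocampus an array was closest to its own number in 7 of 7 pairs of control and of levetiracetam rats. The fewest were 3 of 6 pairs, between control hippocampus and frontal cortex. Same-numbered arrays thus probably share a rat. With the rat as a random replicate block (correlation 0.0598), 2568 probe sets differed between regions for phenytoin, 14 for levetiracetam, and 10732, 11164 and 8903 between regions of control rats.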

Other observations

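The clock gene list, its score with and without Dbp, the opposite-arm and actin tests and the interval over resampled arrays were chosen after the results were seen; the criterion for the Gapdh covariate and the counts over other splits were set before.

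Of 10 genes whose transcription the circadian clock drives, 10 stood below control with levetiracetam in the brainstem and 9 each in the hippocampus and the frontal cortex, where 0 passed over all genes; the exceptions were Tef at 0.18 in the hippocampus and Hlf at 0.07 in the frontal cortex. Dbp stood at a log2 fold change of -0.63 in brainstem, -0.43 in hippocampus and -0.60 in frontal cortex, Nr1d1, which encodes a nuclear receptor of the clock, at -0.41, -0.30 and -0.48, and Usp2 at -0.30, -0.18 and -0.44; with phenytoin Dbp stood at -0.34, 0.13 and -0.53 and Per3 at -0.38, 0.20 and -0.31. A score of these output genes without Dbp, whose small p had prompted the list, minus 4 genes of the opposite phase (Bmal1, Npas2, Clock and Nfil3) differed from control by -0.332 in the brainstem (exact permutation p = 0.00408, n = 7 against 7), -0.190 in the hippocampus (exact permutation p = 0.00641, n = 7 against 7) and -0.357 in the frontal cortex (exact permutation p = 0.0140, n = 7 against 6). After adjustment over 9 comparisons these p were 0.0184, 0.0192 and 0.0252, and with phenytoin the score differed from control by 0.006, 0.02 and -0.163 and did not pass. The regions probably share rats, so their values are not independent of each other. Between the drugs the score was higher with phenytoin by 0.338 in the brainstem (exact permutation p = 0.0134, 0.0252 after adjustment), 0.21 in the hippocampus (exact permutation p = 0.00408, 0.0184 after adjustment) and 0.194 in the frontal cortex (exact permutation p = 0.0973, 0.146 after adjustment).

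RNA integrity stays open: the score with Dbp kept 1.055 of its difference with the Gapdh ratio as a covariate, but that ratio did not differ between these groups and could remove little, and with the actin ratio, which differed by 0.118 in the brainstem, the difference there kept 1.18 of its size (interval over resampled arrays 0.703 to 1.77). Against it as a cause in all regions, the actin ratio differed by -0.018 in the hippocampus (exact permutation p = 0.868) and -0.054 in the frontal cortex (exact permutation p = 0.585), where the score fell too. Time of day of sampling is a candidate explanation that these values do not decide: the opposite arm stood at a mean of 0.06, with 8 of 12 values above 0 and 4 below. The labels give no sampling times, so sampling time and drug cannot be told apart. An effect of levetiracetam on clock output stays open.

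For the counts of probe sets, 100 splits of the same arrays were drawn, the real split included. In the brainstem no other split reached the real count for levetiracetam (1721 against at most 274) or for the drugs against each other (555 against 481). For phenytoin the real count was 3, another split gave 15, and 2 splits, the real one included, gave as many. Chance is thus not excluded for it, and the count itself was 0 with values as deposited and 1 without a filter. In the hippocampus no other split reached the real count for phenytoin (1721 against 46) or between the drugs (3123 against 205). For levetiracetam, with a count of 0, all 100 splits reach it and the splits (at most 2 in another) decide nothing. In the frontal cortex no other split reached the real count for phenytoin (1191 against 305). Between the drugs 2 splits, the real one included, gave as many (2011 against 2711), so chance is not excluded. For levetiracetam, again at 0, all 100 splits reach it (at most 3791 in another). Which arrays the splits with 2711 and 3791 probe sets separate was not tested. For phenytoin effects that differ between regions no other split reached the real count (2266 against 571). The same held for the regions of control rats (10509 against 7733, 10965 against 7724 and 8579 against 4767). For levetiracetam effects that differ between regions 3 splits, the real one included, gave as many (12 against 60). Chance is thus not excluded for them, and the count was 2 without a filter. In an earlier draw of splits under another seed the highest other counts were 25 for phenytoin (1 split gave as many) and 1602 for levetiracetam (4 splits).

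For the gene lists of phenytoin in the brainstem 3 splits, the real one included, gave as many (8 against 9 in another split), which meets the same criterion. Of these 8 lists 0 shifted with an estimated correlation and 0 with fry. Chance is not excluded for them, nor for phenytoin and levetiracetam in the hippocampus (4 against 16, 96 splits, and 4 against 7, 18 splits). The same holds for levetiracetam in the frontal cortex (4 against 20, 77 splits). For levetiracetam in the brainstem (at most 6 in another split) and phenytoin in the frontal cortex (at most 16) the real count is 0, which all 100 splits reach, so they decide nothing.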
